A study of Caenorhabditis elegans and Caenorhabditis briggsae with 14 samples.

How the data were processed

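Embryos of C. elegans (wild type and mutants of ceh-9, mec-3 and M03D4.4) and of C. briggsae AF16 were dissociated and profiled by 10x Genomics single-cell RNA sequencing, 14 libraries in all. The authors made the deposited matrix with Cell Ranger 8.0.0 and Seurat 5 per their processing notes; genome builds, annotations and mapping settings are not stated. The deposited matrix holds counts, whole UMI counts per gene and cell, and the deposited cell table holds the total UMI counts per cell, which equalled the matrix sums in 100% of cells. The authors also deposited the mitochondrial fraction of each cell, an estimated embryo time in minutes, a cell type shared by both species, and a mark for doublet, damaged, stressed or mutant cells. The gene table pairs 13679 C. elegans genes with 1 C. briggsae gene each and lists 6305 genes of C. elegans alone and 7154 of C. briggsae alone.

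The cell table holds 425174 cells of 21 batches, of which 85968 cells of 7 batches belong to no library of this series and were not used. Of the 339206 cells of this series, 308378 carry no mark, 11488 are marked doublet, 5831 damaged, 13490 mutant and 19 stressed. Mutant marks fell on 41.4% of the cells of the 500 minute and 22.3% of the 300 minute M03D4.4 library. The species comparison used unmarked cells with an estimated time from 270 to under 580 minutes (60662 of C. elegans, 112539 of C. briggsae), and the mutant comparisons used unmarked cells and those marked mutant at any time. 65 cells have no estimated time.

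UMIs were summed per library over the cells of each class (body wall muscle, epidermis, ciliated neurons, non-ciliated neurons, glia, pharynx, intestine, from the authors' cell types), and the library was the unit of replication. A library entered a class with at least 30 cells, and the target cells of a mutant with at least 10. Orthologs, or all C. elegans genes for the mutants, were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test) in R 4.3.3 with limma 3.58.1 and Matrix 1.6.5, and called at a Benjamini-Hochberg adjusted p under 0.05. The covariate was the centred mean estimated time of the summed cells per 60 minutes, so a fold is at the average time and can differ in sign from the difference of the mean CPM. The C. elegans libraries of all genotypes formed 1 side of the species comparison, because wild type has 1 library. No paired analysis was possible because the labels give no numbers that pair libraries of the 2 species.

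The class by species interaction was an F test over the same sums with the library as a fixed block. Gene lists were tested on the species contrast with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over 199 list and class pairs. The 33 lists are ribosome, proteasome, respiratory chain, mitochondrial genome, histones, chaperones, dissociation stress, sarcomere, pharyngeal muscle and cuticle, cuticle collagens, hedgehog-related and patched-related, immune effectors, detoxification, lipid metabolism, lysosomal and digestive proteases, V-ATPase, cilia, chemoreceptors, guanylate cyclases, touch receptor, neuropeptides, neurotransmitter synthesis and transport, synaptic and dense-core vesicle, ligand-gated channels, homeobox, nuclear hormone receptors, bHLH, T-box, GATA and endoderm, cell cycle, apoptosis and engulfment, maternal embryonic regulators, and P granule and germline.

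The expression distance was a Jensen-Shannon distance between pooled ortholog shares of a cell type, thinned to 100000 UMIs in 5 draws, less the mean distance between sets of libraries of one species. Classes were compared over cell types with 100000 permutations, or all of them where few. Embryo times were compared with nominal times by Pearson and Spearman correlation with exact permutation of the pairings, and class shares carry Clopper-Pearson 95% intervals.

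Genes were named by a rule. For each class these were its marker genes, then the 4 highest and 4 lowest folds among called genes with a symbol, an average log2 CPM of at least 5 and no overlap between the libraries of the species. For the shared difference these were the 6 highest and 6 lowest mean folds among genes so called in every class, and for the tissue-dependent difference the 12 largest ranges of the fold over classes. For the lists, 2 to 4 members with the largest called folds qualified, and those printed were taken, after their values were seen, from members whose fold and mean levels went the same way. For the mutants these were the targeted gene, the touch receptor list for mec-3, and the 5 called genes with the smallest p in each direction.

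On simulated data made from these libraries, with 200 changed genes, the species tests recovered 65 to 94% of genes changed by a log2 fold of 2 and 9 to 44% of those changed by 1, and called at most 0.0795% of unchanged genes. The mutant tests recovered 46 to 70% at a log2 fold of 2 and 86 to 94% at 4. These rates hold for the simulated data alone. Among splits of the real libraries other than by species, the highest count was 2756 calls, in intestine. Libraries were checked for duplicates, and the lowest chi-square per degree of freedom between 2 libraries was 94.0.

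The alternatives tried were DESeq2 1.42.0 size factors and Wald test, no low-count filter, no time covariate, and the nominal time as a group. Others were a window from 330 to under 510 minutes, at least 100 cells, and cell types weighted alike. Libraries were also thinned to the smallest total, and each library was left out. For the distance they were 50000 UMIs, a Euclidean distance, 1 minus the Spearman correlation, cells of all times, and leaving out the mutant with the most cells. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Positions are from the WBcel235 assembly, Ensembl release 115. The groups, comparisons and their tests, lists, naming rule and these alternatives were set before the data were examined. The printed examples of the lists and some tests of technical explanations were chosen later.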

Results

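Single-cell RNA sequencing with the 10x Genomics droplet method was applied to whole embryos of 2 nematodes, Caenorhabditis elegans and Caenorhabditis briggsae, whose embryos share nearly the same cell lineage. The series holds 14 libraries. The 7 C. elegans libraries are 1 wild-type library (N2 VC2010, 600 minutes), 2 libraries of the ceh-9 mutant (tm2747, 300 and 600 minutes), 2 of the mec-3 mutant (gk1126, 300 and 600 minutes) and 2 of the M03D4.4 mutant (gk5269, 300 and 500 minutes). The 7 C. briggsae libraries are of the strain AF16, at 120, 180, 240, 300, 360, 400 and 500 minutes. Each nominal time has 1 library per genotype.

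The deposited table holds 339206 cells of these libraries. Total UMIs (unique molecular identifiers, 1 per captured molecule) were 14424703 in the 300 minute and 71518201 in the 500 minute M03D4.4 library, 63307814 in the wild-type library, 42608784 and 49576396 in the 300 and 600 minute ceh-9 libraries, and 39467144 and 49410157 in the 300 and 600 minute mec-3 libraries. The C. briggsae libraries, in order of nominal time, held 89427566, 71915957, 71521509, 31535207, 44126953, 24811680 and 36725318 UMIs. Median UMIs per cell ran from 803 in the 300 minute M03D4.4 library to 1773 in the 500 minute one, and from 841 to 1657 in C. briggsae. One-to-one orthologs took from 92.2 to 95.1% of the UMIs of the C. elegans libraries. In C. briggsae they took from 89.5 to 90.5% in 5 libraries, 78.8% in the 240 minute and 77.1% in the 360 minute library.

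The species comparison asked which orthologs differ in level between the embryos, in each of 7 classes of cells. Folds are given as log2 of C. briggsae over C. elegans with the standard error of the fit, at the average embryo time of the libraries, for cells with an estimated time from 270 to under 580 minutes. Calls are at a Benjamini-Hochberg adjusted p under 0.05 in the edgeR quasi-likelihood test. The p-values measure only the spread between these libraries, which may be technical, and each library holds 1 species. For every gene named below as among the largest differences, every library of one species lay above every library of the other. Where one species had no UMI, the fold is that of the summed UMIs without the time covariate, a lower bound against 3 counts over the group, which can differ from the fitted fold, and with 1 to 3 UMIs the ratio is given with its 95% counting interval, which covers counting error only. No share of free RNA from other cells was subtracted from the sums of a class. The C. elegans cells were older on average in all 7 classes, with mean times of 465 against 419 minutes in muscle, 435 against 368 in epidermis, 452 against 424 in ciliated neurons, 455 against 401 in non-ciliated neurons, 470 against 452 in glia, 455 against 428 in pharynx and 407 against 365 in intestine. Of the 35 genes named as among the largest differences of a class, 25 are near absent from one species over the classes, where counts lost to the annotation or mapping of one genome are not excluded.

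In body wall muscle hlh-1, the MyoD homolog, had a fold of -0.14 ± 0.318 (adjusted p = 0.723), and the myosin heavy chain genes unc-54 and myo-3 had 0.01 ± 0.343 (adjusted p = 0.987) and -0.59 ± 0.377 (adjusted p = 0.186). Without the time covariate unc-54 had -1.01 and pat-10 -0.52. With it pat-10, troponin C of body wall muscle, was higher in C. briggsae by 0.83 ± 0.270 (adjusted p = 0.0153), although its mean level was 42980 ± 25400 CPM (scaled UMI counts, SD, n = 5) in C. elegans and 30190 ± 8330 CPM (n = 7) in C. briggsae. daf-42 rose from 0.324 to 316.4 CPM (fold 11.04 ± 0.549, adjusted p = 5.37e-10). fis-1, a mitochondrial fission factor, had 0 UMIs in C. elegans and 2669 in C. briggsae, at least 331-fold higher, and gipc-2 and nlp-27, a peptide gene of the nlp-29 cluster of antimicrobial peptides, were at least 357-fold and at least 261-fold higher. In C. briggsae these 2 genes had 84.6 and 62.2 CPM in muscle, against 545.1 CPM of gipc-2 in ciliated neurons and 4662 CPM of nlp-27 in the epidermis, and free RNA was not excluded as their source in muscle.

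In the other direction, smo-1, the gene of the small modifier SUMO, had 1135 UMIs in C. elegans and 0 in C. briggsae (at least 1018-fold lower), and nuo-2, a subunit of mitochondrial complex I, was at least 2374-fold lower. The small heat-shock gene hsp-12.1 fell from 1820 ± 788 to 0.260 ± 0.381 CPM (fold -12.61 ± 0.580, adjusted p = 4.52e-10), and cnt-2, an ArfGAP, had 1482 against 1 UMI, a ratio of 3987 (714 to 157600). The edgeR test called 5028 of 8535 orthologs, 2762 higher in C. briggsae and 2266 higher in C. elegans, with 4251 over 2-fold. This test set 5 C. elegans libraries against 7, with 1883726 to 6126236 UMIs per library.

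In the epidermis dpy-5, a cuticle collagen gene, was lower in C. briggsae (-6.60 ± 0.908, adjusted p = 2.11e-05), as were sym-1, which encodes a secreted leucine-rich repeat protein (-2.24 ± 0.378, adjusted p = 1.4e-04), and the GATA factor elt-3 (-1.07 ± 0.336, adjusted p = 0.0128). The epidermal zinc finger gene lin-26 was higher (1.64 ± 0.338, adjusted p = 7.4e-04). The collagen gene dpy-7 (-1.06 ± 0.485, adjusted p = 0.0719) and the apical matrix gene noah-1 (-0.96 ± 0.425, adjusted p = 0.0651) did not pass. nlp-27 rose from 12.1 ± 20.8 to 4662 ± 735 CPM (fold 14.51 ± 2.10, adjusted p = 3.44e-05). stdh-4, a steroid dehydrogenase homolog, was at least 2473-fold higher, srlf-12 at least 721-fold, and gsto-2, an omega-class glutathione transferase, had 11223 against 3 UMIs, a ratio of 1639 (561 to 7951). bgnt-1.2, a glycosyltransferase gene, was at least 6309-fold lower in C. briggsae (329.8 ± 246 CPM against 0, fitted fold -12.17 ± 0.718), the short-chain dehydrogenases dhs-6 and dhs-8 at least 2910-fold and 2293-fold lower, and smo-1 at least 2437-fold lower. The edgeR test called 5248 of 9135 orthologs, 2790 higher in C. briggsae and 2458 higher in C. elegans, with 4374 over 2-fold, from 7 libraries of each species.

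In ciliated sensory neurons che-2, a gene of ciliary transport, was lower in C. briggsae (-0.91 ± 0.192, adjusted p = 3.57e-04), and osm-6 (-0.33 ± 0.211, adjusted p = 0.167), che-13 (0.38 ± 0.222, adjusted p = 0.139), dyf-1 (0.35 ± 0.226, adjusted p = 0.171) and bbs-2 (-0.43 ± 0.214, adjusted p = 0.0825) did not pass. The F-box gene fbxb-81 was at least 357-fold higher, btb-19 had 1001 against 1 UMI (ratio 958, 172 to 37880), gipc-2 had 2281 against 1 UMI (ratio 2183, 392 to 86280), and droe-4 rose from 6.17 ± 14.5 to 1087 ± 462 CPM (fold 9.83 ± 0.704, adjusted p = 4.24e-09). snt-6, a synaptotagmin homolog, had 3613 UMIs in C. elegans and 1 in C. briggsae (ratio 3775, 677 to 149100). The SET domain gene set-19 and pcrg-1, homolog of the Parkin co-regulated gene, were at least 302-fold and 358-fold lower, and cnt-2 had 1795 against 2 UMIs (ratio 938, 259 to 7748). In this class edgeR called 4668 of 6864 orthologs (68%), 2395 higher and 2273 lower in C. briggsae, with 3733 over 2-fold.

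In non-ciliated neurons sbt-1, the 7B2 chaperone of peptide processing, was lower in C. briggsae (-1.05 ± 0.281, adjusted p = 0.00326). The kinesin unc-104 (-0.54 ± 0.241, adjusted p = 0.0591) and the SNAP-25 gene ric-4 (-0.69 ± 0.300, adjusted p = 0.0540) did not pass. The carboxypeptidase gene egl-21 (1.28 ± 0.419, adjusted p = 0.0131) and the synaptotagmin gene snt-1 (1.10 ± 0.422, adjusted p = 0.0300) were called higher in C. briggsae, but their mean levels were lower there, at 302.6 against 497.7 CPM and 23.9 against 376.0 CPM, and without the time covariate their folds were -0.87 and -4.08. stdh-4 and fis-1 were at least 470-fold and 354-fold higher, gipc-2 had 1567 against 2 UMIs (ratio 712, 197 to 5880), and pax-2, a paired box factor, rose from 10.7 ± 19.1 to 653.4 ± 184 CPM (fold 11.47 ± 1.14, adjusted p = 5.06e-07). cnt-2, the messenger RNA capping enzyme gene cel-1 and the proteasome ubiquitin receptor rpn-13 were at least 911-fold, 558-fold and 442-fold lower, and smo-1 had 1 against 1349 UMIs (ratio 1485, 266 to 58720). Calls by edgeR numbered 4991 of 8108 orthologs, 2513 higher and 2478 lower in C. briggsae, with 4362 over 2-fold. The count was 1789 when only the 3 cell types that every library held entered, with equal weight, and 2714 when all libraries were thinned to the smallest total.

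In glia mls-2, a homeobox gene of glial development, was lower in C. briggsae (-2.0 ± 0.508, adjusted p = 0.00381) and ptr-10, a patched-related gene, was higher (1.29 ± 0.462, adjusted p = 0.0289). The patched-related gene daf-6 (-0.49 ± 0.557, adjusted p = 0.491) and the potassium-chloride cotransporter gene kcc-3 (0.76 ± 0.423, adjusted p = 0.146) did not pass. pax-2 had 3039 against 3 UMIs (ratio 788, 270 to 3826), gst-2, a glutathione transferase, 237 against 1 (ratio 184, 32.8 to 7317), droe-4 rose from 1.33 ± 3.53 to 2797 ± 491 CPM (fold 9.62 ± 0.669, adjusted p = 3.61e-08), and gur-5, a gustatory receptor homolog, was at least 124-fold higher. cnt-2, smo-1 and aly-1, an RNA export factor gene, were at least 504-fold, 120-fold and 116-fold lower, and spig-9 had 3208 against 3 UMIs (ratio 1374, 470 to 6665). The edgeR test called 2270 of 4818 orthologs, 1249 higher and 1021 lower in C. briggsae, with 2182 over 2-fold. Glia had the smallest sums, 21367 to 838097 UMIs from 44 to 812 cells, and thinning every library to the smallest total left 316 calls, while testing without the low-count filter gave 3473.

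In the pharynx the muscle genes myo-2, a pharyngeal myosin, and tnt-4, a troponin T, were lower in C. briggsae (-1.2 ± 0.416, adjusted p = 0.0211, and -1.04 ± 0.370, adjusted p = 0.0246). The organ's transcription factors ceh-22 (0.45 ± 0.188, adjusted p = 0.0502) and pha-4 (-0.36 ± 0.199, adjusted p = 0.132) did not pass. gst-2 had 24588 UMIs in C. briggsae and 0 in C. elegans, at least 1932-fold higher. The RNA-binding gene gld-1 and pals-38 were at least 61.5-fold and 74.2-fold higher, and the chemoreceptor homolog srsx-17, at 2 UMIs in C. elegans, was higher (ratio 226, 62.5 to 1868). gst-7, also a glutathione transferase, had 2917 UMIs in C. elegans and 1 in C. briggsae (ratio 12370, 2219 to 488900), nuo-2 and the mitochondrial ribosomal gene mrpl-12 were at least 1478-fold and 735-fold lower, and cnt-2 had 1656 against 2 UMIs (ratio 3512, 971 to 29030). By edgeR, 4526 of 7723 orthologs were called, 2424 higher and 2102 lower in C. briggsae, with 3657 over 2-fold, from 5 against 7 libraries. With at least 100 cells per library the count was 2256, and without the 300 minute ceh-9 library the fold of myo-2 was 0.03.

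In the intestine elt-7, a GATA factor of the gut, was lower in C. briggsae (-1.81 ± 0.252, adjusted p = 1.34e-05). The GATA factor elt-2 (-0.31 ± 0.197, adjusted p = 0.179), the intermediate filament gene ifb-2 (-0.29 ± 0.228, adjusted p = 0.291), the esterase gene ges-1 (-0.36 ± 0.228, adjusted p = 0.184) and the aspartyl protease gene asp-1 (-1.06 ± 0.553, adjusted p = 0.110) did not pass. dsl-1, a ligand of the Notch receptor family, had 9884 UMIs in C. briggsae and 0 in C. elegans, at least 1282-fold higher, nlp-27 was at least 217-fold higher (79.5 CPM in C. briggsae), dlc-5, a dynein light chain gene, had 3520 against 1 UMI (ratio 1370, 246 to 54110), and srsx-17 had 3282 against 3 (ratio 426, 146 to 2065). gst-7 had 13308 against 1 UMI, a ratio of 34200 (6137 to 1351000), and dod-3 5211 against 1 (ratio 13390, 2403 to 529100). smo-1 and mrpl-12 were at least 2210-fold and 1472-fold lower. The edgeR test called 4873 of 8094 orthologs, 2612 higher and 2261 lower in C. briggsae, with 3742 over 2-fold, from 375427 to 5949745 UMIs per library.

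The fitted fold and the mean levels pointed opposite ways for 220 called orthologs in body wall muscle, 537 in the epidermis, 142 in ciliated neurons, 487 in non-ciliated neurons, 25 in glia, 57 in the pharynx and 231 in the intestine. With DESeq2 size factors in place of TMM, the median fold of all tested genes moved from 0.01 to 0.23 in non-ciliated neurons and from 0.01 to 0.28 in glia. The share of calls that were higher in C. briggsae moved from 50.3 to 57.5% in non-ciliated neurons and from 55.0 to 64.6% in glia. The balance of directions in these classes therefore depends on the scaling.

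Some orthologs differed in the same direction in every class. spe-5, a paralog of the V-ATPase B subunit, was higher in C. briggsae by a mean of 7.15 ± 1.04 (SD over 7 classes), ebp-1, a microtubule end-binding protein gene, by 4.83 ± 0.972, arrd-1, an arrestin domain gene, by 4.83 ± 1.66, the GPI transamidase gene pigk-1 by 4.69 ± 0.429 and erl-1 by 4.62 ± 0.951. nlp-27 was called higher in all 7 classes, with 4662 CPM in the epidermis and from 49.5 to 137.6 CPM in the other 6, where free RNA from the epidermis was not excluded. eri-12 was lower in C. briggsae by -5.92 ± 0.931, and aco-2, mitochondrial aconitase, was lower in every class (531.3 ± 141 against 0.234 ± 0.121 CPM in body wall muscle, n = 5 and 7). smo-1, cnt-2, nuo-2 and cel-1 were lower in every class, with at most 2 UMIs of each per class in C. briggsae. Of these 12 genes, 7 (spe-5, nlp-27, aco-2, smo-1, cnt-2, nuo-2 and cel-1) are near absent from one species over the classes, where annotation or mapping is not excluded. Of 4166 orthologs tested in all classes, 607 were called higher in C. briggsae in all 7 and 448 lower, and 766 were over 2-fold in the same direction in all. The classes share the 14 libraries and are not independent, with a Pearson correlation of the folds across genes of 0.765 to 0.932 between 2 classes. 240 were called in none.

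The genomic positions of these genes in the WBcel235 assembly, all protein-coding, are as follows. spe-5 lies on chromosome I from 5101665 to 5103476, smo-1 on I from 1340678 to 1341265, nuo-2 on I from 6530131 to 6531963 and cel-1 on I from 9665251 to 9668650. arrd-1 lies on II from 627505 to 628658, cnt-2 on III from 10655018 to 10677523 and aco-2 on III from 7973717 to 7977355. erl-1 lies on IV from 12287928 to 12289392, pigk-1 on IV from 11108085 to 11110018 and eri-12 on IV from 12156838 to 12164281. ebp-1 lies on V from 18043571 to 18052718 and nlp-27 on V from 3989378 to 3989770.

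The species difference also varied by class. This was tested on a different set of genes from the shared counts, and a gene can be in both, so their shares cannot be compared. bgnt-1.2 (chromosome V, 2115486 to 2118674) was an epidermal gene in C. elegans, at 329.8 ± 246 CPM (n = 7), and had at most 3.78 CPM in any other class of either species. Over the classes it is near absent from C. briggsae (8351 against 21 UMIs), where annotation or mapping is not excluded. dod-3 (V, 2730622 to 2731098) had 387.6 ± 326 CPM in the C. elegans intestine against 0.0915 ± 0.242 in C. briggsae, while in ciliated neurons it had 0.983 against 14.6 CPM. daf-42 (IV, 7333638 to 7346851) was higher in C. briggsae muscle (316.4 against 0.324 CPM) and lower in its glia (15.5 ± 14.3 against 203.6 ± 264 CPM, fold -3.69 ± 0.799, adjusted p = 0.00125). nlp-40 (I, 11495 to 16837), a neuropeptide gene of the gut, was lower in the C. briggsae intestine (-4.97 ± 0.543, adjusted p = 1.75e-06) and higher in its pharynx (3.03 ± 0.618, adjusted p = 5.93e-04). acox-1.5 (III, 9586618 to 9592192), a peroxisomal acyl-CoA oxidase gene, was higher in ciliated neurons (3.96 ± 0.332, adjusted p = 6.26e-09) and lower in the intestine (-3.37 ± 0.471, adjusted p = 2.02e-05), and ttr-20 (IV, 4246793 to 4247490), a transthyretin-related gene, was lower in the epidermis (-4.48 ± 0.432, adjusted p = 6.36e-07) and higher in the intestine (4.95 ± 0.367, adjusted p = 1.21e-08).

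gst-2 (IV, 10140330 to 10142061) was higher in C. briggsae in 6 of the 7 classes by the test within the class, from 15.5 CPM in muscle to 1518 ± 1020 in the pharynx, and was not tested in ciliated neurons. Over the classes it is near absent from C. elegans (337 against 41139 UMIs), where annotation or mapping is not excluded. dsl-1 (IV, 1207218 to 1208080) reached 464.3 ± 337 CPM in the C. briggsae intestine and at most 17.2 CPM elsewhere. flp-8 (X, 14881419 to 14882267), a FMRFamide-like peptide gene, had 379.5 ± 352 CPM in C. elegans non-ciliated neurons against 32.5 ± 52.7 (fold -0.76 ± 0.928, adjusted p = 0.493), and was higher in the C. briggsae pharynx (4.79 ± 0.563, adjusted p = 3.6e-06). The hedgehog-related genes wrt-9 (X, 1576637 to 1591320) and grl-21 (IV, 10737474 to 10738191) had 766.5 ± 822 and 582.8 ± 1000 CPM in the C. elegans epidermis against 71.8 ± 55.2 and 0.257 ± 0.419 in C. briggsae, but the fitted fold of wrt-9 there was 0.40 ± 0.512 (adjusted p = 0.518) and grl-21 was not tested in that class. srlf-3 (IV, 8487483 to 8488490) had 1119 ± 1900 CPM in C. elegans glia and 3.46 ± 4.59 in C. briggsae, but its fitted fold there was -1.68 ± 0.692 (adjusted p = 0.0547). The plot of tissue-dependent orthologs shows 6 of these genes in every library.

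**Figure D1:**
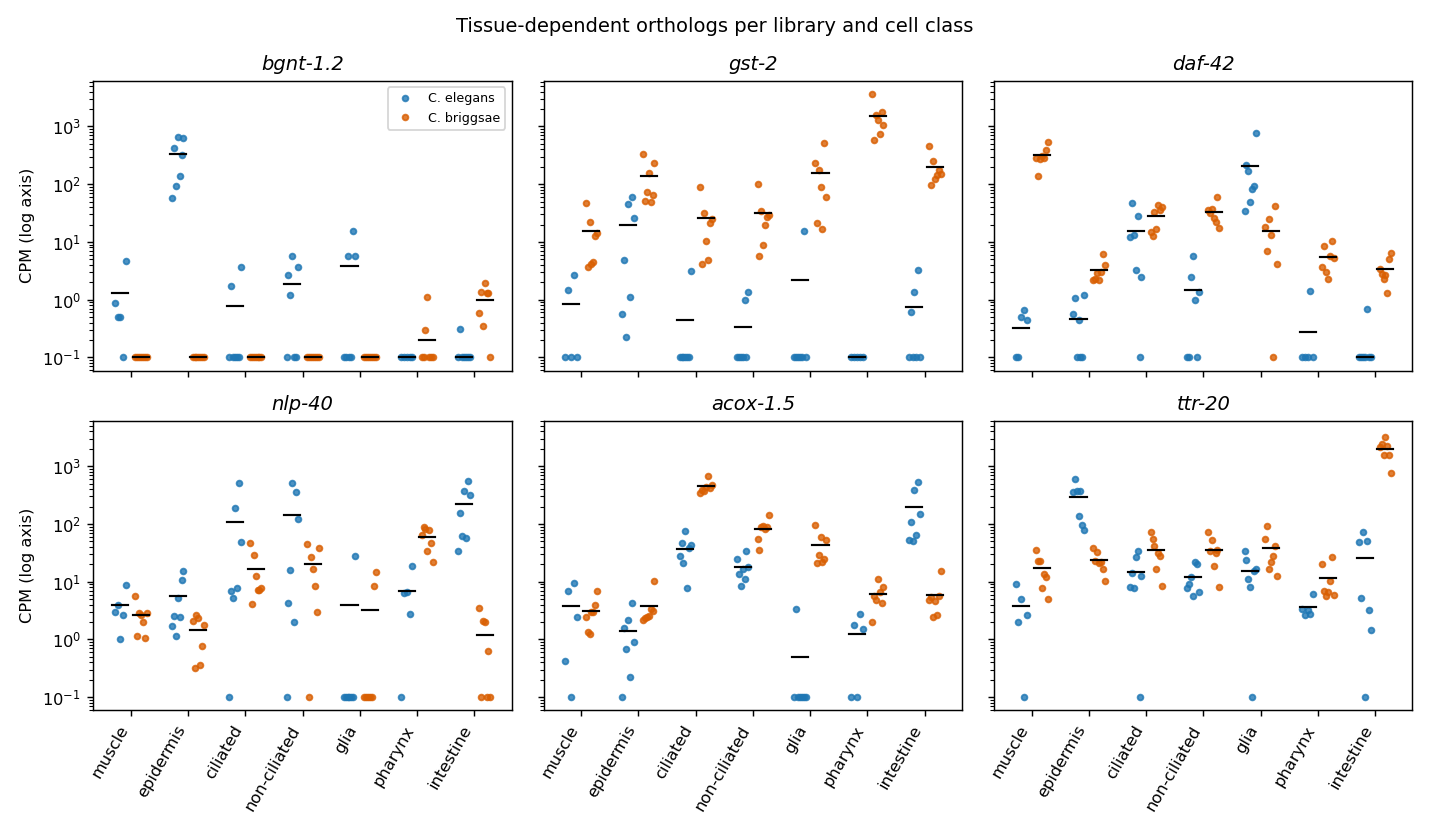
CPM (log axis, values below 0.1 drawn at 0.1) of 6 orthologs in the 7 cell classes, 1 point per library in blue for C. elegans and orange for C. briggsae, with the mean of each species as a black line. bgnt-1.2 stands out in the C. elegans epidermis at a mean of 329.8 CPM and gst-2 in the C. briggsae pharynx at a mean of 1518 CPM. Both genes are near absent from the other species, where annotation or mapping is not excluded.

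The class by species interaction, tested with edgeR over 94 sums of 14 libraries with the library as a block, was called for 8736 of 10981 orthologs (79.6%), without a time covariate, of which 8289 had folds that ranged over 2-fold or more across classes and 5897 over 4-fold or more. With a time covariate for each class it was called for 7344 of 11589. Of the 4166 orthologs tested in all classes, 406 were called in both directions in different classes. Set against the mean of the other classes, C. briggsae was relatively higher for 1231 orthologs and relatively lower for 1351 by more than 2-fold in the intestine, 637 and 1827 in the epidermis, and 971 and 795 in the pharynx.

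Of 33 gene lists fixed before the data were examined, ribosomal protein genes were called lower in C. briggsae in every class by camera at its preset correlation of 0.01, and in none at an estimated correlation (every adjusted p = 0.992). In body wall muscle 67 of 77 were lower and 5 higher (median fold -1.55, camera adjusted p = 3.98e-12), as rps-9 (-2.38 ± 0.235, adjusted p = 6.86e-07) and rpl-35 (-2.41 ± 0.329, adjusted p = 1.81e-05). The numbers lower and higher were 60 and 5 in the epidermis (median -1.34, camera adjusted p = 6.19e-06), 59 and 5 in the intestine (median -1.2, camera adjusted p = 1.64e-07), 58 and 6 in the pharynx (median -0.89, camera adjusted p = 1.64e-07), 48 and 6 in non-ciliated neurons (median -0.81, camera adjusted p = 0.00322), 34 and 6 in ciliated neurons (median -0.52, camera adjusted p = 0.0357) and 16 and 6 in glia (median -0.70, camera adjusted p = 0.0343, 0.0520 with DESeq2 size factors). rla-1, an acidic stalk protein, went the other way, by 2.75 ± 0.245 (adjusted p = 2.26e-07) in the pharynx. Adjusted over the list alone, 38 gene and class pairs were higher and 334 lower, against 39 and 342 over all genes.

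Cuticle collagen genes were called higher in C. briggsae in 4 classes by camera at the preset correlation, and in none at an estimated correlation (every adjusted p = 0.992). In body wall muscle 32 of 52 were higher and 3 lower (median 2.29, camera adjusted p = 0.0105), in non-ciliated neurons 30 and 2 of 41 (median 2.57, camera adjusted p = 0.00106), in ciliated neurons 18 and 1 of 27 (median 2.10, camera adjusted p = 0.0464) and in the intestine 18 and 0 of 28 (median 2.26, camera adjusted p = 0.0343). bli-6, a cuticle collagen gene, was at least 42.1-fold higher in ciliated and at least 63-fold higher in non-ciliated neurons, and col-68 was lower in body wall muscle (-5.95 ± 0.290, adjusted p = 4.49e-10). In the epidermis itself 36 of 91 were higher and 21 lower (median 1.35, camera adjusted p = 0.366), in glia 7 of 35 were higher and 10 lower (median 0.66, camera adjusted p = 0.979), and in the pharynx 10 and 2 of 25 (median 1.82, camera adjusted p = 0.414). The epidermal collagen gene dpy-7 had mean levels of 1415 CPM in C. elegans and 1146 CPM in C. briggsae epidermis. Without TMM scaling these were 1368 and 1371 CPM, and on that scale it had 2.43 and 26.4 CPM in muscle, 11.5 and 41.7 in ciliated and 10.6 and 49.9 in non-ciliated neurons, and 2.05 and 26.5 in the intestine. Free RNA from the epidermis was not excluded as a source of the collagen UMIs in these 4 classes. With DESeq2 size factors the camera adjusted p in ciliated neurons was 0.0519. Adjusted over the list alone, 150 gene and class pairs were higher and 38 lower, against 151 and 39 over all genes.

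Camera called 7 further list and class pairs at the preset correlation, and none of them at an estimated correlation (every adjusted p = 0.992). Immune effectors were higher in the C. briggsae epidermis, 20 of 34 with 4 lower (median 1.81, camera adjusted p = 0.0464, 0.0519 with DESeq2 size factors), as the lysozyme ilys-5 (12.71 ± 1.36, adjusted p = 1.87e-06) and the antimicrobial peptide gene cnc-4 (6.09 ± 0.896, adjusted p = 3.93e-05). In non-ciliated neurons 11 of 13 genes of pharyngeal muscle and cuticle were higher (median 4.00, camera adjusted p = 0.0336), as phat-1 (8.80 ± 1.17, adjusted p = 3.66e-06), which in C. briggsae had 22.4 CPM there, 187.5 in the pharynx and 8.52 to 13.8 in muscle, epidermis and intestine, and 16 of 27 hedgehog-related and patched-related genes were higher with 3 lower (median 2.27, camera adjusted p = 0.0464, 0.0722 with DESeq2 size factors), as grl-14 (5.07 ± 0.637, adjusted p = 1.95e-06). In glia 17 of 25 cilia genes were higher and 1 lower (median 2.52, camera adjusted p = 0.00839), as the dynein component xbx-1 (4.80 ± 0.771, adjusted p = 9.1e-05) and dyf-13 (4.29 ± 0.848, adjusted p = 5.86e-04). Without TMM scaling the cilia gene osm-6 had 32.6 CPM in C. briggsae glia and 537.1 CPM in its ciliated neurons. UMIs from other cells were not excluded for any of the 7 further list and class pairs, among them those of cilia and of pharyngeal muscle and cuticle. In the pharynx 9 of 12 genes of the mitochondrial genome were higher (median 1.0, camera adjusted p = 0.0357), as nduo-5 (3.71 ± 0.341, adjusted p = 3.02e-07). The median mitochondrial percent of the cells was 2.07 to 4.33 in the C. briggsae libraries and 1.08 to 1.80 in the C. elegans libraries. In the pharynx 25 of 43 sarcomere genes were lower and 3 higher (median -0.88, camera adjusted p = 0.0169), as unc-52, perlecan (-4.0 ± 0.411, adjusted p = 9.48e-07), and unc-22, twitchin (-3.13 ± 0.257, adjusted p = 9.61e-08), and 14 of 28 synaptic vesicle genes were lower and 2 higher (median -0.90, camera adjusted p = 0.0343), as unc-13 (-5.99 ± 0.448, adjusted p = 3.8e-08).

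These camera calls, 18 of 199 list and class pairs with the preset correlation of 0.01, rest on that preset. With an estimated correlation camera called 0 pairs (every adjusted p = 0.992), with 3 at an unadjusted p under 0.05, and with DESeq2 size factors it called 14. The fry test called 64 pairs as moved on balance in one direction and 187 as changed in either direction.

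The other lists are given as gene and class pairs summed over the classes unless a class is named, with the count adjusted over the list alone in brackets. Of the lists camera called, immune effectors had 80 higher and 30 lower in C. briggsae of 177 (81 and 32), pharyngeal muscle and cuticle genes 48 and 6 of 77 (50 and 6), hedgehog-related and patched-related genes 77 and 39 of 217 (74 and 35), cilia genes 59 and 76 of 272 (59 and 73), genes of the mitochondrial genome 49 and 7 of 84 (51 and 8), sarcomere genes 42 and 84 of 281 (42 and 82) and synaptic vesicle genes 43 and 53 of 173 (43 and 53). Proteasome subunits had 73 and 40 of 224 (70 and 39), with pas-7 at 3.16 ± 0.375 and rpn-13 at -7.83 ± 0.433 in the intestine. Respiratory chain subunits had 81 and 111 of 249 (83 and 1.1e+02, rounded), and in the intestine 18 and 11 of 37 (18 and 11), with ucr-11 at 3.67 ± 0.415 and nuo-2 at least 1223-fold lower there. V-ATPase subunits had 29 and 27 of 124 (28 and 29), with vha-3 at 2.62 ± 0.275 in the intestine. Histone genes had 1 and 28 of 44 (2 and 29), with the H3.3 gene his-72 at -2.68 ± 0.398 and his-74 at -5.41 ± 0.450 in the epidermis. Chaperone genes had 69 and 99 of 332 (68 and 98), with the chaperonin gene cct-4 at -2.16 ± 0.243 in the epidermis. The dissociation stress list had 0 and 4 of 21 (0 and 3), with hsp-1 at -0.95 ± 0.262 in ciliated neurons. hsp-70 took 0.0999 and 0.159% of the UMIs of the 240 and 360 minute C. briggsae libraries and at most 0.00155% in the other 5.

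**Figure D2:**
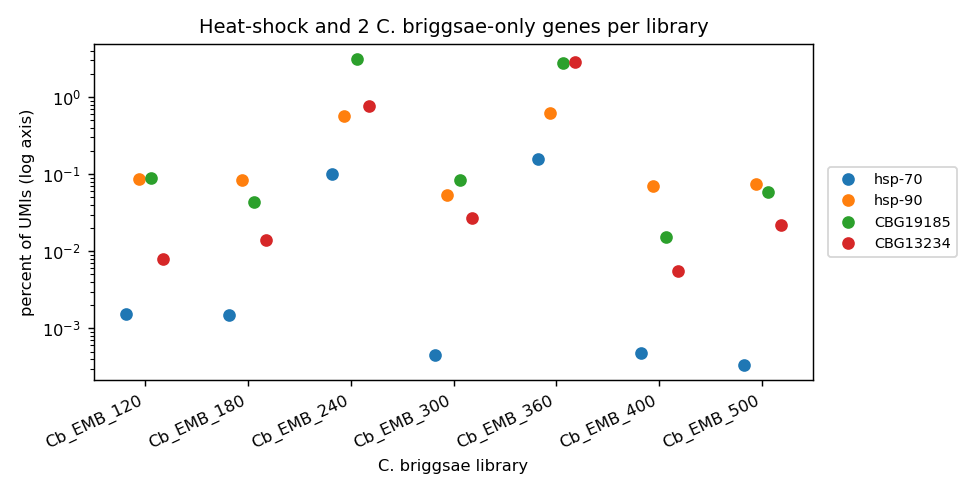
Percent of UMIs (log axis) of hsp-70, hsp-90, CBG19185 and CBG13234 in each C. briggsae library. The 240 and 360 minute libraries lie above the other 5 for all 4 genes.

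Among transcription factors, homeobox genes had 76 and 79 of 342 (72 and 78), with ceh-17 at -5.58 ± 0.319 and ceh-54 at 4.18 ± 0.471 in non-ciliated neurons. Nuclear hormone receptors had 206 and 175 of 645 (210 and 175), with nhr-112 at 6.73 ± 0.846 in the intestine and nhr-219 at least 137-fold higher there. bHLH factors had 9 and 24 of 94 (9 and 23), with hlh-30, the TFEB homolog, at -3.95 ± 0.360 in ciliated neurons. T-box factors had 7 and 4 of 21 (6 and 4), with tbx-7 at 3.31 ± 0.546 in the pharynx. GATA and endoderm factors had 9 and 9 of 35 (10 and 10), with elt-6 at 1.48 ± 0.263 in the epidermis. Among neuronal lists, neuropeptides in non-ciliated neurons had 35 and 17 of 81 (35 and 17), with flp-13 at 7.41 ± 0.679, and neurotransmitter genes 11 and 4 of 37 (11 and 4), with unc-46, needed for GABA loading of vesicles, at least 488-fold lower. Ligand-gated channels had 73 and 36 of 185 (74 and 35), with glr-3 at 4.27 ± 0.685. Chemoreceptors had 127 and 61 of 240 (127 and 66), with srt-43 at least 74.7-fold higher in ciliated neurons. Guanylate cyclases had 8 and 11 of 37 (8 and 10), with gcy-28 at -1.58 ± 0.306. Touch receptor genes had 10 and 9 of 42 (11 and 7), with mec-9 at -3.80 ± 0.540 in non-ciliated neurons. The C. elegans side includes the 2 mec-3 libraries, where mec-10, mec-17, mec-18 and mtd-1 were called lower in non-ciliated neurons. Genotype was therefore not separated from species for the touch receptor list. Detoxification genes in the intestine had 30 and 19 of 80 (32 and 19), with ugt-37 at 7.78 ± 0.808, lipid metabolism genes 48 and 24 of 156 (46 and 24), with the desaturase fat-5 at -5.57 ± 0.885, and lysosomal and digestive proteases 34 and 5 of 59 (35 and 5), with asp-5 at -3.02 ± 0.978. Cell cycle genes had 43 and 79 of 290 (38 and 70), with the kinase inhibitor cki-2 at least 1050-fold lower in the epidermis, apoptosis genes 25 and 19 of 95 (24 and 18), with ced-8 at 2.22 ± 0.347, P granule genes 11 and 9 of 22 (11 and 10), with gld-2 at -1.44 ± 0.246 in the pharynx, and maternal regulators 2 and 18 of 28 (2 and 18), with mex-3 at -1.54 ± 0.416 in the epidermis. Of the genes named from the lists, bli-6 is near absent from C. elegans over the classes. nuo-2, rpn-13, unc-46 and cki-2 are near absent from C. briggsae, and annotation or mapping is not excluded for any of these genes.

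The expression distance asked in which cell types the whole profile differs most between the species. It is a Jensen-Shannon distance between ortholog UMI shares thinned to 100000 UMIs, less the mean distance between 2 sets of libraries of one species. The highest excess was in the AVG interneuron (0.227), in body wall muscle of the posterior (0.221) and of the head (0.215), in the amphid sheath glia (0.214) and in the ADL sensory neuron (0.214). This order depends on the measure, since 3 of these 5 types were among the 5 highest with a Euclidean distance and 2 with 1 minus the Spearman correlation. It also depends on which types enter, since 0 were among the 5 highest with 50000 UMIs, where 62 types entered. Over the 38 types shared with that setting the order was nearly the same (Spearman correlation 0.991). The lowest excess was in the hypodermis (0.0872), the marginal cells mc2a (0.0961), hyp7 of the C lineage (0.102), seam cells (0.113) and far posterior muscle (0.133). All 38 cell types had an excess above 0, with a mean of 0.177 ± 0.0366 (SD, n = 38) on a mean distance of 0.456. Epidermal types lay 0.0302 below the others (-0.0302, two-sided permutation p = 0.0274, adjusted p = 0.110, 9 types), non-ciliated neurons 0.0274 above (permutation p = 0.118, adjusted p = 0.235, 5 types), muscle 0.0113 above (permutation p = 0.383, adjusted p = 0.511, 12 types) and intestine 0.00244 above (exact p = 0.904, adjusted p = 0.904, 4 types). No class passed at an adjusted p under 0.05 in these permutation tests, 1 of the 4 having an unadjusted p under 0.05. The permutations treat cell types as independent, although all come from the same libraries. Their p-values measure the spread over cell types and not over libraries. In hyp7 of the C lineage and mc2a, the distance between C. elegans libraries (0.468 and 0.422) exceeded that between species (0.442 and 0.417). In the 5 types of lowest excess this C. elegans distance was 0.422 to 0.468, against 0.209 to 0.256 between C. briggsae libraries. The C. elegans libraries differ in nominal time, and stage was not separated from this baseline. A low excess, in these types or in the epidermis, therefore cannot be read as a smaller species difference.

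The mutants were each compared with the other 5 C. elegans libraries, with the mean estimated time as a covariate, since wild type has 1 library. mec-3 encodes a LIM homeodomain factor needed for touch receptor neurons (chromosome IV, 10458816 to 10461867, minus strand). In the ALM, PLM and ALM or BDU cells mec-17, a tubulin acetyltransferase gene, had 0 UMIs in mec-3 and 40226 in the others, where it averaged 88090 ± 129000 CPM (n = 5, adjusted p = 1.69e-09, at least 1692-fold lower). mec-18, mtd-1, mec-2, mec-9, mec-10 and C03A3.3 were also at 0 UMIs in mec-3 and at least 185-fold, 246-fold, 82.4-fold, 80.7-fold, 79-fold and 98.2-fold lower, as was the homeobox gene alr-1 (at least 30.4-fold, adjusted p = 1.74e-05). These bounds and the ratios below come from UMIs summed without matching embryo time, so they do not bound the effect of genotype alone. The 300 and 600 minute mec-3 libraries gave 69591 and 7296 UMIs in these cells. Without TMM scaling mec-10 had 167 and 665 CPM in the 300 minute M03D4.4 and ceh-9 libraries. It had 5333 and 3135 CPM in the 600 minute ceh-9 and wild-type libraries. The degenerin channel gene mec-4 had 1 against 1298 UMIs (ratio 164, 29.4 to 6475, adjusted p = 2.74e-05) and mec-14 had 1 against 521 (ratio 65.8, 11.8 to 2602, adjusted p = 0.00636). mec-1 fell by 3.03 ± 0.792 (adjusted p = 0.00922). Without TMM scaling mec-1 had 43.1 and 1234 CPM in the 300 and 600 minute mec-3 libraries. On that scale it had 1083 and 1167 CPM in the M03D4.4, 2121 and 9082 CPM in the ceh-9 and 6489 CPM in the wild-type libraries. In ALM_PLM cells alone mec-14 (adjusted p = 0.0759) and mec-1 (adjusted p = 0.0755) did not pass. The tubulin genes mec-12 (-1.81 ± 0.743, adjusted p = 0.252) and mec-7 (-1.21 ± 0.780, adjusted p = 0.638) and the tau homolog ptl-1 (2.17 ± 0.927, adjusted p = 0.275) did not pass.

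mec-3 itself was detected in these cells of the mec-3 libraries (2120 CPM, range 1636 to 2605, against 4854 ± 4020, fold -0.31 ± 0.616, adjusted p = 0.957). Over whole libraries it had 11.1 and 2.73 CPM in the 300 and 600 minute mec-3 libraries and from 9.15 to 79.3 CPM in the others. Of the 14 genes called higher in the same cells, 5 were counted by cell. nlp-49 had 26 UMIs in 1 cell and flp-1 16 UMIs in 1 cell of the 600 minute mec-3 library, while the 600 minute ceh-9 library also had 52 UMIs of nlp-49 in 1 cell and 54 of flp-1 in 2 cells, and Y72A10A.1, ten-1 and hil-5 had 13, 20 and 8 UMIs over both mec-3 libraries. The edgeR test called 39 of 1898 genes in these cells, 14 higher and 25 lower. In non-ciliated neurons it called 5, all lower: mec-10 (-11.79, adjusted p = 0.0162), mec-17 (-7.92, adjusted p = 0.0162), mec-18 (-5.86, adjusted p = 0.0106), mtd-1 (-8.15, adjusted p = 0.0360) and T07D1.3 (-4.89, adjusted p = 0.0162). In the other 6 classes it called 0, with 229 genes at an unadjusted p under 0.05 in muscle, 241 in the epidermis, 161 in ciliated neurons, 120 in glia, 577 in the pharynx and 159 in the intestine.

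The target cells numbered 64 and 13 in the mec-3 libraries and 57, 197, 67, 133 and 346 in the others. The total of 44 calls was 43 with the DESeq2 Wald test, 0 with the nominal time as a group, 72 without the low-count filter, 27 without the 500 minute M03D4.4 library, 23 without the 300 minute ceh-9 library, 18 without the 300 minute and 83 without the 600 minute mec-3 library. Those 18 were all in the target cells (12 higher and 6 lower). Without the 600 minute mec-3 library all 83 were in the pharynx (6 higher and 77 lower), and edgeR called 0 in the target cells, with 140 genes at an unadjusted p under 0.05, where Y72A10A.1 had a fold of -1.47. In non-ciliated neurons edgeR called 0 without either mec-3 library or without the 500 minute M03D4.4 library, with 376, 1.2e+02 (rounded) and 182 such genes.

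**Figure D3:**
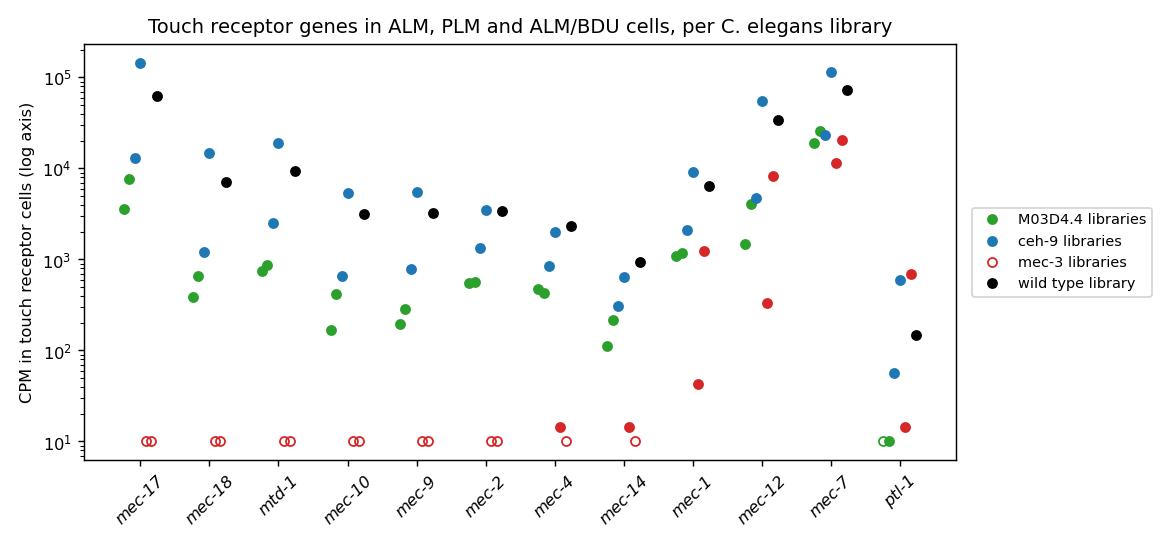
CPM (log axis) of 12 touch receptor genes in ALM, PLM and ALM or BDU cells, 1 point per C. elegans library, with open circles at the lower edge for 0 UMIs. Both mec-3 libraries lie at 0 for mec-17, mec-18, mtd-1, mec-10, mec-9 and mec-2.

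ceh-9 encodes a homeodomain factor (chromosome I, 565284 to 566588, minus strand). F15A4.5 was the one gene called in the ceh-9 libraries, in ciliated neurons, with 0 UMIs against 2178 in the other 5 libraries (241.8 ± 277 CPM, n = 5, edgeR adjusted p = 0.0466). ceh-9 itself was detected, at 6.92 and 3.78 CPM in the 300 and 600 minute ceh-9 libraries and from 1.99 to 19.9 CPM in the others, and in non-ciliated neurons at 135.4 CPM (134.2 to 136.5) against 82.0 ± 44.8 (fold 0.64 ± 0.465, adjusted p = 0.999). In CAN, the cell type with the highest ceh-9 level in other genotypes among those well filled in both ceh-9 libraries, edgeR called 0 of 1865 genes, with 58 at an unadjusted p under 0.05. That level was 29.7 CPM, from 20 UMIs in 543 cells, and ceh-9 itself was too low to be tested in CAN. In the other 6 classes it called 0, with 59 such genes in muscle, 137 in the epidermis, 213 in non-ciliated neurons, 428 in glia, 179 in the pharynx and 168 in the intestine. The total of 1 call was 5 with the DESeq2 Wald test, 0 with the nominal time as a group, 1.2e+02 (rounded) without the low-count filter, 8 and 2 without the 300 and 600 minute ceh-9 library, 13 and 4 without the 300 and 600 minute mec-3 library, and 5 without the wild-type library. The 8 and 2 calls were in CAN and the 13 in glia. F15A4.5 was no longer called in ciliated neurons without the 300 or 600 minute ceh-9 library, the 300 or 600 minute mec-3 library or the 500 minute M03D4.4 library, where edgeR called 0 in that class, with 201, 223, 253, 328 and 144 genes at an unadjusted p under 0.05.

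M03D4.4, which encodes a zinc finger protein (chromosome IV, 6121773 to 6127302, minus strand), gave the most calls. The 500 minute M03D4.4 library held the M03D4.4 transcript at a level near that of the wild-type library, at 377 against 388 CPM. These values are of body wall muscle cells of 300 to under 420 minutes, thinned to 1000 UMIs. The calls therefore cannot be read as the effect of losing M03D4.4. In the GLR_2 cells lbp-1, a lipid-binding protein gene, had 22700 CPM (10690 to 34710, n = 2) in the M03D4.4 libraries against 379.1 ± 211 (n = 3, fold 5.88 ± 0.530, edgeR adjusted p = 4.17e-10). In these cells the chemoreceptor homolog srg-51 had 85 against 3 UMIs (ratio 42.9, 14.2 to 212), the claudin homolog clc-3 72 against 3 (ratio 36.3, 11.9 to 180.2), and the transporter gene slc-17.1 was higher by 4.25 ± 0.594 (adjusted p = 4.38e-06), while the small heat-shock gene hsp-16.2 had 2 against 79 UMIs (ratio 26.1, 6.99 to 219) and C24A3.2 was lower by -2.37 ± 0.488 (adjusted p = 0.00208). Over whole libraries hsp-16.2 took 0.0803 and 0.00391% of UMIs in the 300 and 500 minute M03D4.4 libraries. The 3 other libraries that entered GLR_2 had 0.159% (300 minute ceh-9), 0.182% (300 minute mec-3) and 0.0505% (wild type). The 500 minute M03D4.4 library thus lay below all 3, and a difference of whole libraries was not separated from the call in GLR_2. The 600 minute ceh-9 and mec-3 libraries, which did not enter GLR_2, had 0.00369 and 0.0151%. Cells marked damaged were 10.3 and 11.9% of the 300 minute ceh-9 and mec-3 libraries and at most 0.249% of the other C. elegans libraries. C42D4.18 had 50 against 2 UMIs there (ratio 37.8, 9.94 to 321). In the intestine Y9C9A.8 (-2.52 ± 0.243, adjusted p = 0.0367) and the cathepsin gene cpr-5 (-3.79 ± 0.433, adjusted p = 0.0472) were lower. In body wall muscle lam-3, a laminin gene, was called lower (-2.65 ± 0.306, adjusted p = 0.0125) at means of 20.8 against 19.3 ± 25.9 CPM, and had 1.49 with the nominal time as a group.

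The calls were 87 in body wall muscle (56 higher and 31 lower), 16 of 969 genes in GLR_2 (12 and 4), 6 in the intestine (2 and 4) and 1 in the pharynx, the chemoreceptor homolog str-18. In the other 4 classes edgeR called 0, with 1018 genes at an unadjusted p under 0.05 in the epidermis, 616 in ciliated neurons, 330 in non-ciliated neurons and 296 in glia. M03D4.4 itself was not called in muscle (-1.44 ± 1.36, adjusted p = 0.720) or in GLR_2 (-1.34 ± 0.716, adjusted p = 0.543). It had 2.34 CPM in the 300 minute and 56.9 CPM in the 500 minute M03D4.4 library, 104.8 and 104.6 CPM in the 300 minute ceh-9 and mec-3 libraries, and 2.23, 1.50 and 4.4 CPM in the 600 minute ceh-9, mec-3 and wild-type libraries. The total of 110 calls was 938 with the DESeq2 Wald test, 201 with the nominal time as a group, 218 without the low-count filter, 1178 and 60 without the 300 and 500 minute M03D4.4 library, 12 and 38 without the 300 and 600 minute ceh-9 library, and 6 without the 300 minute mec-3 library. In body wall muscle edgeR called 0 without the 300 minute ceh-9 library, with 698 genes at an unadjusted p under 0.05, and 0 without the 300 minute mec-3 library, with 749 such genes, so the 87 muscle calls rest on both of these libraries.

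**Figure D4:**
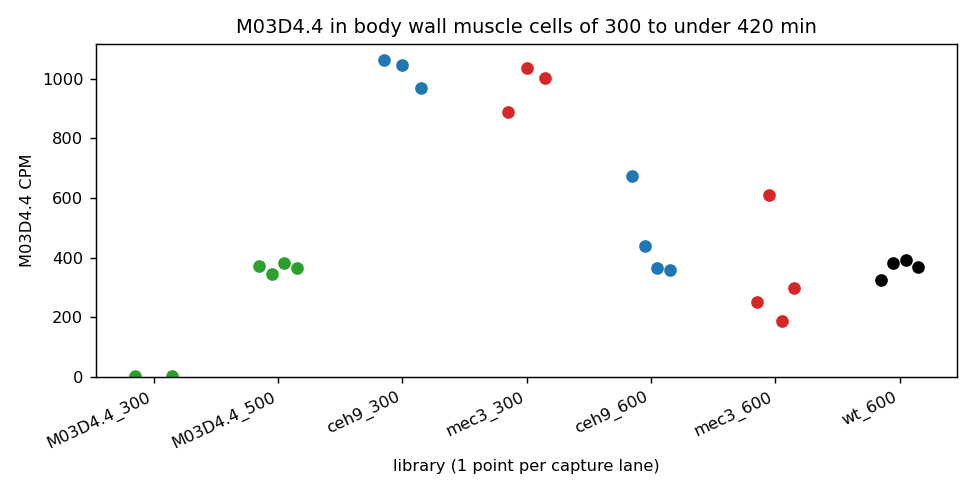
CPM of M03D4.4 in body wall muscle cells with an estimated time from 300 to under 420 minutes, 1 point per capture lane of each C. elegans library. The lanes of the 300 minute M03D4.4 library lie at 2.46 and 2.95 CPM and those of the 500 minute library from 344 to 380 CPM.

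The estimated embryo time of the cells, made by the authors from expression, was compared with the nominal time of the library. Over the 7 C. elegans libraries the medians ran from 330 to 630 minutes. These libraries fall in separate clusters, 3 at 300 minutes and 4 at 500 to 600 minutes, with medians of 330 to 342.5 and of 425 to 630 minutes. The Pearson and Spearman relations over all 7 passed (exact pairings p = 0.0143, adjusted p = 0.0286 for each), but they rest on the difference between the clusters, and each cluster has too few libraries for a test within it. Over the 7 C. briggsae libraries the medians ran from 260 to 400 minutes, with Pearson r = 0.546 (exact pairings p = 0.196, adjusted p = 0.221) and Spearman rho = 0.541 (exact p = 0.221, adjusted p = 0.221; 4 relations in the family), and r = 0.524 (exact p = 0.400) without the 2 libraries farthest from the median nominal time. The library labelled 120 minutes had a median of 347.5 minutes.

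Body wall muscle held from 19.5% of the typed cells in the 500 minute C. briggsae library (Clopper-Pearson 95% interval 19 to 20.1) to 55.9% in the 600 minute mec-3 library (55.3 to 56.5). In the 500 minute C. briggsae library non-ciliated neurons held 33.7% (33.1 to 34.4), pharynx 10.8% (10.4 to 11.2), ciliated neurons 12.6% (12.2 to 13.1), epidermis 9.72% (9.31 to 10.1) and intestine 1.57% (1.40 to 1.75). In the 120 minute C. briggsae library epidermis held 29.2% (28.5 to 29.9), muscle 25.7% (25.1 to 26.4), non-ciliated neurons 12.1% (11.6 to 12.6), intestine 8.27% (7.87 to 8.69) and pharynx 3.52% (3.25 to 3.8). With 1 library per time the intervals cover counting error only. Among cells with at least 1000 UMIs, 6 of the 14 libraries kept the same largest class.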

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

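The test of a constant factor was chosen after the result was seen. The tests of free RNA and of the mix of cell types, and the counts over other splits, were set before.

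The species difference depended on the class for 8736 orthologs by the interaction test. That test has no time covariate and the C. elegans cells were older by amounts that differ between classes, so the count mixes class with stage, and it was 7344 with a time covariate for each class. The range of the log2 fold over classes was 15.51 for bgnt-1.2, 14.76 for dod-3, 13.50 for daf-42, 12.62 for gst-2, 11.83 for nlp-40, 11.11 for dsl-1, 10.92 for flp-8, 10.63 for acox-1.5, 10.54 for wrt-9, 10.50 for grl-21, 10.47 for srlf-3 and 10.23 for ttr-20. These ranges are of fitted values, and for bgnt-1.2, dod-3, gst-2, dsl-1, flp-8, acox-1.5, wrt-9 and grl-21 they rest in part on a class with 3 or fewer UMIs in one species. bgnt-1.2 and gst-2 are also near absent from one species over the classes, where annotation or mapping is not excluded. Within a class and with the time covariate, wrt-9 in the epidermis (adjusted p = 0.518) and srlf-3 in glia (adjusted p = 0.0547) did not pass.

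Of 4166 orthologs tested in all classes, 179 (4.30%, 3.70 to 4.96) were called over 2-fold in opposite directions in different classes, as daf-42 and ttr-20. A single factor per gene from annotation or mapping would be the same in every class, so genes picked for opposite calls in one set of libraries would keep the order of those classes in the remaining libraries no more often than not. All 95 genes picked in the ceh-9 and M03D4.4 libraries and the C. briggsae libraries of 120, 240, 360 and 500 minutes (100%, 96.2 to 100) and all 21 picked in the remaining libraries (100%, 83.9 to 100) kept it, which argues against such a factor as the whole cause for these genes. A first form of this test asked for over 5% of opposite calls and was not met, at 4.30%; a second form used the interaction count, which restates the observation, and was dropped. In 15 genes (8.38%, 4.77 to 13.4) a call rested on a class below 5% of the species' own highest class. This argues against free RNA from other cells below that share as the cause for most of the genes. A higher share of free RNA was not tested, and calls of sym-1 and dpy-2 rested on 8.85 and 7.77% in C. briggsae. A different mix of cell types is argued against by the 135 of 139 genes (97.1%, 92.8 to 99.2) that had both directions in 6 classes with the 1 to 13 cell types that every library held weighted alike, and a difference in regulation between the species, or in the cells that each type holds, stays open and untested.

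For each comparison 25 splits of the libraries were counted, the real one included, and in each 1 split, the real one, gave as many calls. A share of 1 in 25 is the smallest that this test can reach. A split that mixes the species also puts their difference into the spread within a group, which lowers its calls. The species grouping gave the most calls, but the test cannot tell species from other differences between the libraries. The real and highest other counts were 5028 and 0 in body wall muscle, 5248 and 1005 in epidermis, 4668 and 0 in ciliated neurons, 4991 and 1274 in non-ciliated neurons, 2270 and 440 in glia, 4526 and 1 in pharynx, 4873 and 2756 in intestine, and 2911 and 431 for the interaction on every 3rd ortholog. The high counts in intestine, non-ciliated neurons and epidermis each came from 1 other split, and their cause was not tested.

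In 5 of 79 groups of 7 libraries tested, 1 library lay far from the others, where chance gives about 1 in 20. The median mitochondrial percent was 4.33 in the 300 minute C. briggsae library and 2.07 to 2.98 in the others. The pharynx share was 10.8% in the 500 minute C. briggsae library and 0.954 to 4.18% in the others. gst-2 in the pharynx had 3618 CPM in the 120 minute C. briggsae library and 572 to 1751 in the others. elt-2 in the intestine had 214 CPM in the 240 minute C. briggsae library and 305 to 358 in the others. nlp-27 in the intestine had 152 CPM in the 400 minute C. briggsae library and 59.2 to 73.8 in the others.

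Genes without an ortholog pair entered no species comparison and still held signal. CBG19185 took 3.10% of the UMIs of the 240 minute C. briggsae library, and the linker histone gene hil-7 took 1.62% of the UMIs of the 500 minute M03D4.4 library.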

How the results depend on the processing

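The alternatives "cells marked mutant kept", "without the 240 and 360 minute C. briggsae libraries", "without the 600 minute libraries" and "ALM_PLM cells alone" were chosen after seeing the data. Of 2377 values of named genes in the species differences under an alternative, 2286 kept their direction and side of the threshold, 44 passed it, 42 no longer did and 5 reversed; for the mutants these were 408, 4, 82 and 2 of 496. Among cells with at least 1000 UMIs, 116 class shares moved out of their counting interval and 10 did not. Without the time covariate, unc-54 (-1.01) and pat-10 (-0.52) in muscle and egl-21 (-0.87) and snt-1 (-4.08) in non-ciliated neurons reversed; leaving out 1 library, myo-2 in pharynx ran from -1.67 to 0.0279 (without the 300 minute ceh-9 library) and Y72A10A.1 from -1.47 (without the 600 minute mec-3 library) to 5.87, and lam-3 was 1.49 with the nominal time as a group. The count in non-ciliated neurons was 1789 with cell types weighted alike, where 3 types entered, and 2714 with libraries thinned to the smallest total, in glia 316 when thinned and 3473 with no low-count filter, where more genes were tested, and in pharynx 2256 with at least 100 cells, where fewer libraries entered. Camera with an estimated correlation called 0 list and class pairs, and the distance called 1 class with a Euclidean measure and 2 with 50000 UMIs. With no low-count filter the mutant counts were 72 for mec-3, 1.2e+02 (rounded) for ceh-9 and 218 for M03D4.4; with the nominal time as a group 0, 0 and 201; with the DESeq2 Wald test 5 for ceh-9 and 938 for M03D4.4; and with ALM_PLM cells alone 29 for mec-3. Among cells with at least 1000 UMIs, 6 of 14 libraries had the same largest class. Where no construction of the setting is named, the cause was not tested. Leaving out each library gave 4310 to 5047 calls in muscle, 4772 to 5548 in epidermis, 4388 to 4912 in ciliated neurons, 4528 to 5194 in non-ciliated neurons, 1914 to 2488 in glia, 3882 to 4550 in pharynx, 4093 to 4929 in intestine, 8054 to 8965 for the interaction, 18 to 83 for mec-3, 1 to 13 for ceh-9 and 6 to 1178 for M03D4.4; a lone mutant library is assumed to vary like the others. Named libraries behind the mutant ranges are given with those results. Cell types could not be weighted alike in glia, and the setting without the 600 minute libraries gave no value in muscle and pharynx. The thinned count of 316 in glia shows the effect of fewer UMIs, and depth was not compared with other limits on the count there.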

Other observations

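The tests of complex subunits, of a wrong label, of a mixture, of capture lanes and of the mutant allele were chosen after the results were seen; the test of overlapping genes was set before.

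In 2 C. briggsae libraries heat-shock transcripts were abundant. hsp-70 took 0.0999 and 0.159% of the UMIs of the 240 and 360 minute libraries and at most 0.00155% in the other 5, and hsp-90 took 0.562 and 0.616% against 0.0541 to 0.0871%. Genes found in C. briggsae alone took 21.2 and 22.9% of their UMIs against 9.47 to 10.5%, with CBG19185 at 3.10 and 2.76% and CBG13234 at 0.767 and 2.87%. In C. elegans hsp-70 reached 0.0103 and 0.0123% in the 300 minute ceh-9 and mec-3 libraries, where hsp-16.41 took 0.248 and 0.263% and hsp-16.2 0.159 and 0.182%, against 0.00311 to 0.132% and 0.00369 to 0.0803% in the other 5. No biological explanation was tested.

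Among 8836 orthologs, 139 were near absent from one species, 33 from C. elegans and 106 from C. briggsae, with a level from summed UMIs, averaged over the classes, under 1% of the other species' and at most 10% of it in each class where the other had at least 1 CPM. eef-1A.1, a translation elongation factor gene, had 302002 UMIs in C. elegans and 68 in C. briggsae, sec-61.G 66179 and 0, and fis-1 0 and 7486. Counts lost to the annotation or mapping of one genome could give this pattern. The test counted subunits of the ribosome, proteasome, V-ATPase, chaperonin and respiratory chain, which cells need. They were 1.44% of these genes (0.175 to 5.10, 2 genes) against 1.95% of all, but 2 genes are too few to decide. Subunits of other complexes were not counted, and the mitochondrial ribosomal gene mrpl-12, also near absent, is one of those left out. Reads shared with an overlapping gene on the same strand cannot be told apart either, with 3.03% (0.0767 to 15.8, 1 of 33) against 2.51%. A loss or gain of expression between the species stays open and untested.

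The library labelled M03D4.4_500 held the M03D4.4 transcript, at 377 CPM in body wall muscle cells of 300 to under 420 minutes thinned to 1000 UMIs, against 8.0 in the 300 minute M03D4.4 library, 388 in wild type, 462 and 556 in the 600 minute ceh-9 and mec-3 libraries (from 26 and 18 cells), and 1033 and 1014 in the 300 minute ceh-9 and mec-3 libraries. On a wrong label, 69 genes set the 2 M03D4.4 libraries apart from the other 5, where the other 11 pairs of libraries had 0 to 2. The pair of ceh-9 libraries and the pair of mec-3 libraries had 0 each, so a shared genotype need not give such genes. The 69 genes show a pattern common to the M03D4.4 libraries, but cannot decide whether genotype or another common factor gave it. A mixture with cells at the level of the 300 minute libraries is argued against by the share of cells with the transcript, 0.501 (0.460 to 0.546) of theirs, above the ratio of CPM of 0.368, and 1 lane of another sample by the lanes, whose lowest was 0.904 of the highest. The level was near that of the wild-type library (30.2 against 29.4% of cells), so the result on a mixture rests on which library is the reference. A transcript made from the mutant allele in both M03D4.4 libraries is argued against by the 0.8% of such cells with it in the 300 minute one (0.0203 to 4.38, 1 UMI in 125 cells) against 30.2% (28.3 to 32.1). A biological difference between these 2 libraries stays open and untested.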
